A study of Mus musculus with 4 samples.

How the data were processed

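Genomic DNA of 4 macrodissected mouse melanomas, 2 with wild-type Dnmt3b and 2 with a floxed Dnmt3b allele, was cut with MspI, treated with bisulfite and size-selected by electrophoresis, per the labels' protocols. The submitters' processing notes name Trim Galore 0.37, BSMAP 2.74, methylKit and build mm10, with no role or order. Each tumour has its own deposited table of cytosines in CpG and other contexts. The deposited counts per cytosine and strand are the reads showing C and the reads showing C or T, with the counts of G and of G or A on the opposite strand, per the file headers. The deposited expected counts are the C or T counts multiplied by the share of G on the opposite strand. The deposited fraction is the methylated count over that expected count, with bounds of an interval around it. Counts stop at 65535, and 124, 123, 60 and 65 positions of WT replicates 1 and 2 and KO replicates 1 and 2 reached that value. Every listed position had at least 1 methylated read, so a cytosine that was read but never methylated is absent from a table. A mean over CpGs listed in all tumours therefore lies above the mean over all CpGs read.

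The whole counts of C and of C or T were used, not the expected counts or the fraction. Both strands of a CpG were summed, and where 1 strand was absent its depth was taken from the opposite-strand counts of the listed strand with no methylated read. In the file of each tumour, 1 position carried a misspelt name of chromosome 1 and was assigned to it. CpGs at the ceiling were left out (30). Of 2050345 CpGs listed in at least 1 tumour, 517054 had at least 10 reads in all 4 and were compared. The median depth of listed CpGs was 19, 22, 19 and 27 reads in WT replicates 1 and 2 and KO replicates 1 and 2. Depth sets counting error only, since reads without molecular identifiers are not independent molecules.

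Genes came from a table of 49980 genes on assembly GRCm38.p6, the assembly of build mm10, which gives no strand or exons. Genome sequence was not used here. Compared tiles that start at 146038001 on chromosome 7 and 120563001 on chromosome 12 lie past the ends of those chromosomes in mm10. The deposited positions thus do not follow mm10, and they were laid over the gene table unconverted. Which build they follow was not examined. Gene names, distances and gene windows therefore rest on position numbers alone and need not be the genes read. Promoters, exons, CpG islands and repeats were therefore not defined. In place of promoters, each gene was tested at the end richer in listed CpGs, from 1000 bp outside to 500 bp inside (gene-end windows), which can be either end of the gene. In place of islands, CpGs were classed by the number of other CpGs listed in any tumour within 500 bp. Gene lists held 490 genes in 14 lists, and 488 matched the gene table by symbol.

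Methylated and unmethylated counts of CpGs, of 1000-bp tiles and of gene-end windows with at least 3 CpGs were compared between WT and KO with edgeR 4.0.16 (quasi-likelihood test, a coefficient per tumour, no trend in the dispersion) in R 4.3.3. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference of mean levels of at least 10 percentage points. A list member passed adjusted over the list alone at an adjusted p under 0.05 among the measured members of its list, with no minimum difference. Levels are methylated reads over all reads, given as mean ± SD of the tumours of a group. Mean levels over many CpGs were compared with an exact two-sided permutation test. Lists were tested with camera in limma 3.58.1 on M-values, log2 of methylated over unmethylated counts with 1 added to each, at a preset correlation of 0.01. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. The groups, tests, lists and most alternatives were fixed before the data were examined. The named genes are the called gene ends with both KO tumours beyond both WT tumours (12 largest falls and rises, all if fewer), Dnmt3b, Rictor and Mir196b, and the 1 or 2 measured members of each list with the largest difference at gene ends.

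Alternatives were the minimum depth, an upper limit on depth, a likelihood ratio test without overdispersion, Fisher's exact test on pooled reads, limma on M-values, autosomes only, other tile and window sizes, strands kept apart, pooled reads and leaving out each tumour in turn. Chosen after seeing the data were flank depth, listed strands only, removal of CpGs with base-change reads, both gene ends and whole genes. Flank depth counts a CpG absent from a table as unmethylated where cytosines within 20 bp on both sides of the same strand were read, and adds 78314 CpGs. Base-change reads are under 80.0% G among at least 10 opposite-strand reads in any tumour. The tests were tested on simulated data at the real depths. Every feature of a group was given that group's average spread between tumours, so differences in spread between features were not simulated. Changes were placed only at features with a low or a high level in WT. The shares below therefore say nothing about features at middle levels. Of tiles changed by 25, 50 and 80 points, 12.9%, 78.6% and 96.7% were recovered among 62578. For gene-end windows the shares were 82.9%, 100% and 100% among 4188. Among all 510708 simulated CpGs none of the changed CpGs was recovered (0%). Among a subset of 19732 CpGs the shares were 12.9%, 51.4% and 91.7%. The real data gave 540 calls among about as many CpGs, so the simulation does not describe the test of single CpGs, and why was not tested. No false call was made at any level. Among all simulated CpGs no call of any kind was made, so this gives no assurance for the 540 real calls.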

Results

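Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation in MspI restriction fragments of genomic DNA, was applied to 4 cutaneous melanomas of C57Bl/6 mice. The tumours were genetically induced, with a mutant Braf allele and a floxed Pten allele. Dnmt3b was wild type in 2 tumours (WT replicates 1 and 2), and 2 tumours also carried a floxed Dnmt3b allele (KO replicates 1 and 2). Dnmt3b encodes a de novo DNA methyltransferase, and the comparison asks which DNA methylation differs between melanomas with and without it. The reads over listed CpG cytosines came to 165134234 and 180170801 in the WT tumours and 138975544 and 141429429 in the KO tumours. A total of 517054 CpGs had at least 10 reads in all 4 tumours. Their autosomal median depth was 112 and 123 reads in WT and 99 and 101 in KO. The titles give each tumour its own number, and nothing else in the labels says how the animals were related. The p-values therefore set the difference between groups against the spread between these tumours. Anything else that separates the WT from the KO tumours, such as the read totals above, cannot be told apart from Dnmt3b status. The number in the title of WT replicate 2 differs from that in the name of its deposited file, and its group was taken from the title. Coordinates are the deposited positions, counted from 1. The submitters name build mm10, but positions such as 146038001 on chromosome 7 lie past the end of that chromosome in mm10. Gene names and distances below therefore say where a position number falls in the mm10 gene table. They need not be the genes read.

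The stretch of chromosome 2 from 153649411 to 153687730, where the gene table places Dnmt3b, was examined first as a check of the labels. Since the deposited positions do not follow the build of that table, the stretch need not be Dnmt3b. Its values therefore cannot serve as that check. Reads were scarce in both KO tumours over 4 neighbouring CpGs inside the stretch, between 153670150 and 153670227. The mean depth there, relative to each tumour's autosomal median, was 1.88 and 1.95 in WT replicates 1 and 2, and 0.386 and 0.252 in KO replicates 1 and 2. KO replicate 1 thus had 20.2% of the WT mean relative depth and KO replicate 2 had 13.2%. At 17 other CpGs of the stretch the KO depth was 92.5% of the WT depth. Among all compared CpGs, 0.0990% of 517054 had a KO to WT depth ratio as low as the mean of these 4. Their position in an exon or intron was not analysed here, and the segment was delimited after its depth was seen. The few reads left in the KO tumours were methylated at 85.7% to 98.0% per CpG in KO replicate 1 and 77.3% to 100% in KO replicate 2. Over the whole stretch with 1000 bp on both sides, the level at 21 CpGs was 76.7% ± 1.21 (SD, n = 2) in WT and 83.5% ± 2.92 (SD, n = 2) in KO. This did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.184). A tile inside the stretch from 153683001 to 153684000, picked after its values were seen, was at 34.6% ± 0.896 (SD, n = 2) in WT and 80.9% ± 10.9 (SD, n = 2) in KO over 3 CpGs. With an adjusted p of 0.0790 in edgeR's quasi-likelihood test over all tiles it was not called.

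**Figure D1:**
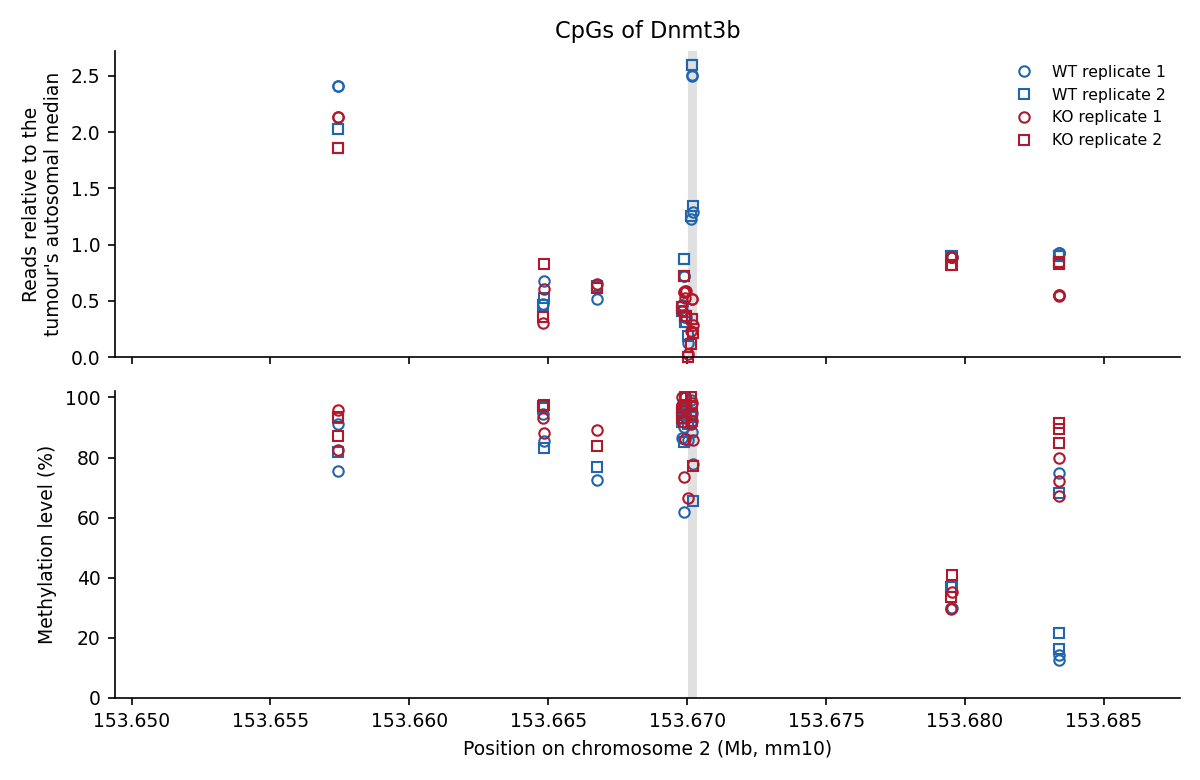
Read depth relative to each tumour's autosomal median (top) and methylation level in percent (bottom), by position on chromosome 2 in Mb. CpGs with at least 10 reads in both WT tumours are shown, from 153649411 to 153687730. The gene table places Dnmt3b there, but the deposited positions do not follow its build. Each symbol is 1 tumour and the grey band marks 153670150 to 153670227. In the band the mean relative depth is 0.386 and 0.252 in the KO tumours and 1.88 and 1.95 in the WT tumours.

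The average methylation level differed between the groups by less than the spread between tumours. Over the 517054 CpGs, each counted once, it was 62.6% and 62.7% in the WT tumours and 62.2% and 63.5% in the KO tumours. The group means were 62.7% ± 0.0463 (SD, n = 2) and 62.8% ± 0.875 (SD, n = 2). The difference, KO minus WT, was 0.176 percentage points, with p = 1 in an exact two-sided permutation test that cannot go below 0.33 with 2 tumours per group. It was 0.795 points without KO replicate 1 and -0.443 points without KO replicate 2. With reads pooled, so that deeply read CpGs counted more, the difference was -2.47 points, and the cause of that change was not tested. Pearson's r across CpGs, which are not independent replicates, was 0.977 between the WT tumours and 0.957 between the KO tumours. KO replicate 1 correlated with WT replicates 1 and 2 at 0.960 and 0.958, and KO replicate 2 at 0.95 and 0.95.

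Autosomal CpGs with 10 or more other listed CpGs within 500 bp had a higher level in both KO tumours than in both WT tumours, most so in DNA dense in CpGs. At the 15672 autosomal CpGs with 60 or more other listed CpGs within 500 bp, the level was 26.6% and 26.5% in WT and 28.3% and 30.1% in KO. The group means were 26.5% ± 0.0640 (SD, n = 2) and 29.2% ± 1.28 (SD, n = 2). At the 77212 autosomal CpGs with 30 to 59 such neighbours it was 48.6% ± 0.0888 (SD, n = 2) in WT and 49.5% ± 0.463 (SD, n = 2) in KO. At the 173461 with 10 to 29 it was 64.14% and 64.19% in WT and 64.22% and 65.06% in KO. At the 217175 with 0 to 9 neighbours it was 69.2% ± 0.133 (SD, n = 2) and 68.9% ± 0.902 (SD, n = 2). Autosomal CpGs at the CpG-richer end of protein-coding genes averaged 53.9% ± 0.0259 (SD, n = 2) in WT and 54.0% ± 0.860 (SD, n = 2) in KO. CpGs inside genes averaged 60.6% ± 0.0828 (SD, n = 2) and 60.9% ± 0.813 (SD, n = 2). CpGs outside genes averaged 65.7% ± 0.0280 (SD, n = 2) and 65.9% ± 0.635 (SD, n = 2). These gene classes rest on the build of the gene table, which the deposited positions do not follow. The exact two-sided permutation p was 1 at 0 to 9 neighbours, and in each class of 10 or more it was 0.33, the smallest that 2 against 2 allows. Over all chromosomes the difference at CpG-dense DNA was 1.48 points, -0.225 without KO replicate 2, 3.19 without KO replicate 1 and -3.91 with reads pooled. These values include the X chromosome, where KO replicate 1 was lower. On autosomes each KO tumour alone, at 28.3% and 30.1%, lay above both WT tumours. No autosomal value with reads pooled was computed.

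The X chromosome of KO replicate 1 stood apart from that of the other 3 tumours. Over 33199 X-linked CpGs the level was 61.5% and 61.4% in the WT tumours, 58.1% in KO replicate 1 and 62.2% in KO replicate 2. At the 3495 X-linked CpGs with 60 or more neighbours it was 30.6% and 30.1% in WT, 21.3% in KO replicate 1 and 31.9% in KO replicate 2. The median depth of X-linked CpGs relative to autosomes was 0.973 and 0.992 in WT, 0.747 in KO replicate 1 and 0.970 in KO replicate 2. In KO replicate 1 alone, 41 Y-linked CpGs had at least 10 reads, so its sample may hold DNA of a male animal. All levels of that tumour, on autosomes too, may then be a mixture. The group difference over the X chromosome was -1.29 points with all tumours and 0.802 without KO replicate 1. The exact two-sided permutation p was 1.

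**Figure D2:**
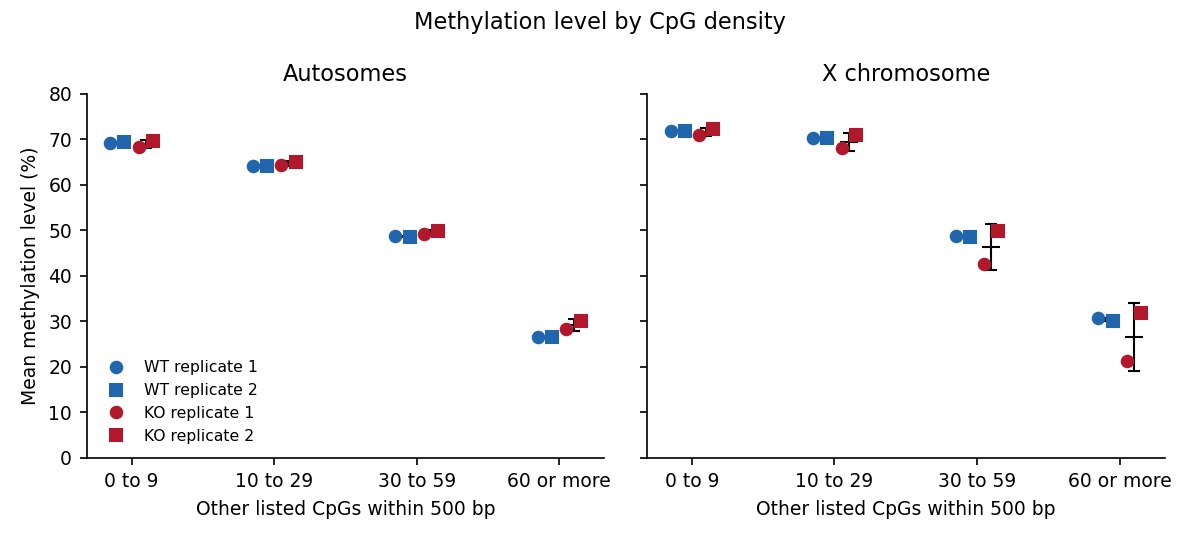
Mean methylation level in percent on autosomes (left) and the X chromosome (right), by the number of other listed CpGs within 500 bp; each coloured symbol is 1 tumour and black bars show the mean and SD of the 2 tumours of a group. At 60 or more neighbours the KO tumours lie at 28.3% and 30.1% on autosomes, above both WT tumours, and KO replicate 1 lies at 21.3% on the X chromosome, below the other 3 tumours.

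Individual CpGs changed in both directions. Of 514400 CpGs tested with edgeR's quasi-likelihood test, 540 passed a Benjamini-Hochberg adjusted p of 0.05 with a difference of at least 10 points, 214 lower and 326 higher in KO. Flank depth, which counts unlisted CpGs as unmethylated, gave 113 lower and 309 higher. Tests that ignore the spread between tumours had more lower than higher, 24252 and 23367 with the likelihood ratio test and 22875 and 21647 with Fisher's exact test on pooled reads. At all 540 of the quasi-likelihood calls both KO tumours lay beyond both WT tumours. At the intervals that the gene table gives as CpG-richer ends of protein-coding genes 2 were lower and 19 higher. The deposited positions do not follow the build of that table, so these intervals need not be gene ends. With 60 or more neighbours 32 were lower and 17 higher. Without the run with the most called CpGs, left out after its values were seen, these were 2 lower and 16 higher. CpGs called higher had a median level of 1.95% in WT and 63.4% in KO, and those called lower 85.7% and 18.9%. Opposite-strand reads of a base change were present at 140 of the called CpGs (25.9%) and at 0.319% of those not called. With such positions removed 335 CpGs were called, all among the 400 called CpGs without such reads. On autosomes alone with them removed 632 were called. Leaving out WT replicate 1 or WT replicate 2 gave 0 calls, with 22450 and 20385 CpGs at an unadjusted p under 0.05. Leaving out KO replicate 1 gave 2731, and limma on M-values called 0, with 49028 at an unadjusted p under 0.05.

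Most called CpGs stood alone, and some formed short runs. Genes named beside the runs follow position numbers in the gene table and need not be the genes read. With called CpGs at most 2000 bp apart joined, 381 were isolated and 159 lay in 53 runs, and the runs named here were chosen after their values were seen. The run with the most called CpGs, 33 of which 32 were lower, lay on chromosome 17 between 39980198 and 39985671. By number this is 24911 bp from Esp38 in the gene table. The mean level of its called CpGs fell from 57.3% ± 0.148 (SD, n = 2) in WT to 23.1% ± 1.71 (SD, n = 2) in KO. Their median depths were 497 and 671 reads in WT and 1503 and 965 in KO. The autosomal medians were far lower, at 112 and 123 reads in WT and 99 and 101 in KO. Whether the run lies in repeated DNA was not analysed, so it need not be a single locus. At 6 CpGs between 134731390 and 134731516 on chromosome 4, 10038 bp from Ldlrap1, which encodes an adaptor of the LDL receptor, the level fell from 50.9% ± 0.451 (SD, n = 2) to 17.4% ± 3.51 (SD, n = 2). At 7 CpGs between 106367485 and 106367724 on chromosome 9, 836 bp outside Dusp7, which encodes a phosphatase of MAP kinases, it rose from 1.19% ± 0.0442 (SD, n = 2) to 16.0% ± 4.10 (SD, n = 2). Inside Rapgef5, which encodes a guanine nucleotide exchange factor, 3 CpGs between 117642998 and 117643038 on chromosome 12 rose from 22.9% ± 1.09 (SD, n = 2) to 85.8% ± 13.8 (SD, n = 2). Inside Tbx1, which encodes a T-box transcription factor, 3 CpGs between 18582246 and 18582653 on chromosome 16 rose from 1.80% ± 0.427 (SD, n = 2) to 15.7% ± 5.67 (SD, n = 2). Inside Eri3, 3 CpGs between 117599377 and 117599402 on chromosome 4 rose from 2.17% ± 0.544 (SD, n = 2) to 18.1% ± 5.44 (SD, n = 2). The largest adjusted p among the called CpGs of these runs was 0.0498 in edgeR's quasi-likelihood test.

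Among 62590 tiles of 1000 bp with at least 3 CpGs, 2 changed, and both were lower in KO. Genes named for tiles are those at the same position numbers in the gene table, and need not be the genes read. The tile from 9528001 to 9529000 on chromosome 13 lies inside Dip2c, and its 3 CpGs fell from 97.3% ± 0.463 (SD, n = 2) in WT to 69.8% ± 3.602 (SD, n = 2) in KO, at 1166 to 1832 reads per tumour. The tile from 125787001 to 125788000 on chromosome 2 lies 4131 bp outside Secisbp2l, and its 13 CpGs fell from 66.2% ± 0.222 (SD, n = 2) to 25.4% ± 1.73 (SD, n = 2). The adjusted p was 0.0469 for both in edgeR's quasi-likelihood test, and 9568 tiles had an unadjusted p under 0.05. The tile near Secisbp2l held 69502 reads in KO replicate 1 beside 3328, 3365 and 3903 in WT replicates 1 and 2 and KO replicate 2. With the CpGs of highest coverage removed its difference was -13.3 points and 0 tiles passed. The difference at Dip2c did not change there, at an adjusted p of 0.0671. With base-change positions removed 0 tiles passed. The tile in Dip2c kept 2 of 3 CpGs and was not tested. The tile near Secisbp2l kept 10 CpGs, at 79.3% ± 0.326 (SD, n = 2) in WT and 40.2% ± 0.413 (SD, n = 2) in KO. Its p was 1.24e-06 in place of 1.50e-06, and its adjusted p rose to 0.0772 because Dip2c, with a p about as low, was no longer tested. Leaving out WT replicate 1 or WT replicate 2 gave 0 tiles, leaving out KO replicate 1 gave 3400 and leaving out KO replicate 2 gave 1945.

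On autosomes alone more tiles passed, 38 lower and 23 higher in KO among 59267. The genes named from this setting were chosen after their values were seen. Their names follow position numbers in the gene table and need not be the genes read. Inside Kif13a, which encodes a kinesin motor protein, a tile from 46908001 on chromosome 13 fell from 63.0% ± 0.803 (SD, n = 2) in WT to 26.9% ± 1.56 (SD, n = 2) in KO. A tile from 94236001 on chromosome 8 inside Nup93, which encodes a nucleoporin, fell from 15.2% ± 0.856 (SD, n = 2) to 4.01% ± 0.449 (SD, n = 2). One from 52597001 on chromosome 13 inside Syk, which encodes a tyrosine kinase, fell from 28.4% ± 3.27 (SD, n = 2) to 9.83% ± 0.593 (SD, n = 2). Inside Scarf2, which encodes a scavenger receptor, 3 tiles on chromosome 16 rose. The tile at 17802001 went from 8.68% ± 2.28 (SD, n = 2) to 27.6% ± 2.31 (SD, n = 2), that at 17806001 from 26.4% ± 4.41 (SD, n = 2) to 54.5% ± 1.18 (SD, n = 2) and that at 17807001 from 19.9% ± 4.03 (SD, n = 2) to 48.2% ± 3.06 (SD, n = 2). Inside Asic1, which encodes an acid-sensing ion channel, a tile from 99693001 on chromosome 15 rose from 19.8% ± 3.68 (SD, n = 2) to 60.5% ± 4.46 (SD, n = 2). Inside Pole, which encodes the catalytic subunit of DNA polymerase epsilon, a tile from 110335001 on chromosome 5 rose from 25.1% ± 4.76 (SD, n = 2) to 59.9% ± 1.67 (SD, n = 2). With base-change positions also removed, 52 autosomal tiles passed.

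At gene-end windows, which cover the CpG-richer end of a gene from 1000 bp outside to 500 bp inside, 4 of 4189 changed, 2 lower and 2 higher in KO. The windows follow the positions of the gene table and need not lie at the genes named. The window of Pyroxd1 (gene on chromosome 6 from 142345627 to 142362729), which encodes a pyridine nucleotide-disulfide oxidoreductase, rose from 4.31% ± 0.694 (SD, n = 2) in WT to 23.1% ± 1.12 (SD, n = 2) in KO over 9 CpGs. It overlaps Recql, which encodes a DNA helicase. The window of B3glct (chromosome 5, 149678100 to 149762599), which encodes a glucosyltransferase, rose from 40.8% ± 1.70 (SD, n = 2) to 72.8% ± 0.0257 (SD, n = 2) over 5 CpGs. The window of Mrm3 (chromosome 11, 76243736 to 76250625), which encodes a mitochondrial ribosomal RNA methyltransferase, fell from 27.7% ± 1.21 (SD, n = 2) to 11.1% ± 0.717 (SD, n = 2) over 8 CpGs. The window of the pseudogene Gm9370 (chromosome 12, 33846324 to 33847259) fell from 32.8% ± 2.24 (SD, n = 2) to 9.90% ± 1.91 (SD, n = 2) over 3 CpGs. Reads per tumour lay between 895 and 1646 at B3glct, 2190 and 3980 at Pyroxd1, 1978 and 2546 at Gm9370 and 5027 and 6110 at Mrm3. In edgeR's quasi-likelihood test the adjusted p was 0.0256 for Pyroxd1 and 0.0454 for B3glct, Mrm3 and Gm9370, with 609 windows at an unadjusted p under 0.05. With base-change positions removed 1 window passed, that of Pyroxd1, and the difference at B3glct was 23.4 points in place of 32.0. The windows of Gm9370 and Mrm3 lost no CpG, their differences stayed at -22.9 and -16.5 points and their p did not rise. Their adjusted p went from 0.0454 to 0.0540 as B3glct ranked lower. With listed strands only, the difference at B3glct was 25.6 points (adjusted p 0.0604), and over the whole gene 7.79 (0.178). At a minimum of 20 reads only Pyroxd1 passed, and the others were at an adjusted p of 0.0518. With unlisted CpGs counted as unmethylated (flank depth) only Pyroxd1 passed again, with Gm9370 and B3glct at 0.0816 and Mrm3 at 0.0901. limma on M-values called 0 windows, with all 4 at an adjusted p of 0.191 and 570 windows at an unadjusted p under 0.05. Leaving out WT replicate 1 or WT replicate 2 gave 0 windows, leaving out KO replicate 1 gave 136 and leaving out KO replicate 2 gave 26.

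**Figure D3:**
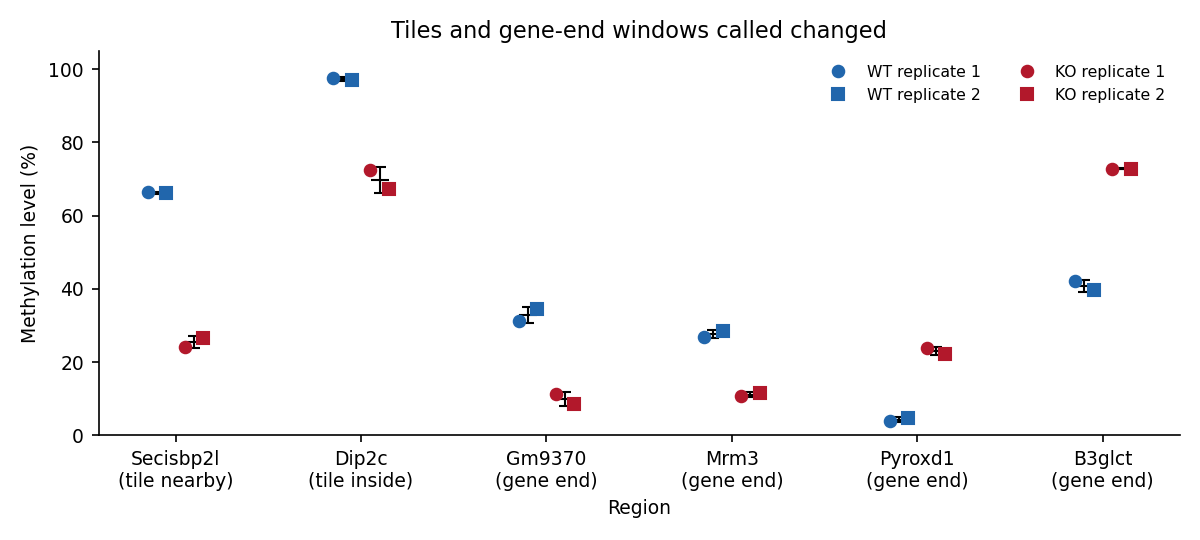
Methylation level in percent of the 2 tiles and the 4 gene-end windows called changed; each coloured symbol is 1 tumour and black bars show the mean and SD of the 2 tumours of a group. The KO tumours lie below the WT tumours at Secisbp2l, Dip2c, Gm9370 and Mrm3 and above them at Pyroxd1 and B3glct. Names follow position numbers in the gene table and need not be the genes read.

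The microRNA gene Mir196b and Rictor, which encodes a subunit of mTOR complex 2, were of interest in the study before the data were examined. Both were looked up where the gene table places them, on a build that the deposited positions do not follow. The stretches searched need not be these genes, so the values below leave both loci unexamined. No CpG within 5000 bp of Mir196b (chromosome 6, 52230081 to 52230165) was listed with at least 10 reads in all 4 tumours, and none with at least 5. CpGs read there but never methylated would be absent from the tables. The nearest CpG with at least 10, 5490 bp away at 52235655, had levels of 71.0% and 84% in WT and 83.3% and 75% in KO, at 31, 25, 24 and 20 reads. Neither end of Rictor (chromosome 15, 6708349 to 6800401) held a listed CpG with at least 10 reads in all 4 tumours. Over 28 CpGs of the whole Rictor gene with 1000 bp on both sides, the level was 79.1% ± 0.394 (SD, n = 2) in WT and 78.1% ± 1.49 (SD, n = 2) in KO, with an adjusted p of 0.774 in edgeR's quasi-likelihood test.

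Few members of the gene lists were measured at gene ends, and none passed the quasi-likelihood test over all windows. Because the deposited positions do not follow the build of the gene table, these windows need not lie at the genes named. The values below therefore cannot be read as the methylation of those genes or cell type markers. Of 12 measured Hox genes, which encode homeobox transcription factors of body patterning, 9 had a higher and 3 a lower mean in KO. Hoxb13 was at 28.8% ± 1.77 (SD, n = 2) in WT and 46.2% ± 13.9 (SD, n = 2) in KO, and Hoxa1 at 22.6% ± 4.58 (SD, n = 2) and 33.2% ± 7.82 (SD, n = 2). The windows of Hoxa10 and Hoxa11 hold the same 17 CpGs and those of Hoxa5 and Hoxa6 overlap. The 12 windows are thus 10 separate stretches of DNA, and camera's test of the Hox genes counts shared CpGs more than once. None passed adjusted over the list alone. Of 14 measured polycomb-regulated developmental transcription factors, 10 had a higher and 4 a lower mean in KO. Olig2 was at 30.1% ± 0.241 (SD, n = 2) in WT and 37.6% ± 5.82 (SD, n = 2) in KO, and Gbx2 at 90.2% ± 1.51 (SD, n = 2) and 93.0% ± 2.90 (SD, n = 2). Again none passed adjusted over the list alone. The 4 measured leukocyte markers all had a lower mean in KO, and Cd68, a macrophage marker, passed adjusted over the list alone, at 37.7% ± 2.48 (SD, n = 2) in WT and 23.8% ± 1.01 (SD, n = 2) in KO. Among 3 measured germline genes Tex12, which encodes a protein of the synaptonemal complex, passed adjusted over the list alone, at 19.2% ± 2.69 (SD, n = 2) in WT and 10.5% ± 1.78 (SD, n = 2) in KO. The test limma offers for lists (camera, preset correlation 0.01, 11 lists) gave an adjusted p of 0.112 for Hox genes (p = 0.0102, towards higher) and 0.232 for leukocyte markers (p = 0.0421, towards lower). It was 0.931 for each of the others. The adjusted p was 0.938 for every list with an estimated correlation.

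In the remaining lists no gene end passed over all windows or adjusted over the list alone. Of 6 tumour suppressor and cancer-methylated genes, 4 had a higher and 2 a lower mean in KO. Rassf1 was at 57.0% ± 1.05 (SD, n = 2) in WT and 43.0% ± 11.03 (SD, n = 2) in KO, and Trp53 at 54.2% ± 5.35 (SD, n = 2) and 66.1% ± 2.24 (SD, n = 2). Of 4 imprinted genes, 2 had a higher and 2 a lower mean in KO, with Cdkn1c at 89.5% ± 1.75 (SD, n = 2) in WT and 77.9% ± 5.47 (SD, n = 2) in KO. Of 4 melanocyte genes, 1 had a higher and 3 a lower mean in KO. Pax3 was at 20.1% ± 0.944 (SD, n = 2) in WT and 27.7% ± 9.84 (SD, n = 2) in KO, and Ednrb at 95.1% ± 0.479 (SD, n = 2) and 91.2% ± 0.665 (SD, n = 2). Of 5 protocadherin genes, 2 had a higher and 3 a lower mean in KO, with Pcdhb11 at 40.4% ± 0.417 (SD, n = 2) in WT and 35.3% ± 5.72 (SD, n = 2) in KO. Of 3 keratinocyte markers, 2 had a higher and 1 a lower mean in KO, with Itgb4 at 47.5% ± 5.53 (SD, n = 2) in WT and 32.5% ± 5.21 (SD, n = 2) in KO. Of 3 fibroblast markers, 1 had a higher and 2 a lower mean in KO, with Prrx1 at 42.3% ± 11.5 (SD, n = 2) in WT and 67.4% ± 18.5 (SD, n = 2) in KO. Of 3 DNA methylation enzymes and readers, 2 had a higher and 1 a lower mean in KO, with Tdg at 78.8% ± 0.129 (SD, n = 2) in WT and 71.4% ± 6.93 (SD, n = 2) in KO. In the mTOR and AKT list 1 gene end was measured, with Mtor at 75.9% ± 8.14 (SD, n = 2) in WT and 77.8% ± 10.1 (SD, n = 2) in KO, and none was measured among endothelial markers or miR-196 genes. The median and mean difference had opposite signs for DNA methylation enzymes, fibroblast markers, germline genes, keratinocyte markers, melanocyte genes and tumour suppressor genes, and camera's direction opposed the mean for fibroblast markers, melanocyte genes and tumour suppressor genes.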

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

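The tests of X depth and of Dnmt3b loss were chosen only after the X-linked values were seen, and the test on Y-linked CpGs was set before its result was seen. Y-linked CpGs gave a signal in 1 tumour: 41 had at least 10 reads in KO replicate 1 alone, beside 1 in WT replicate 1 alone, 1 in WT replicate 2 alone and 0 in KO replicate 2 alone. They lay between 233376 and 2886891 on chromosome Y, at a median of 21 reads against 99 at autosomal CpGs of that tumour. In all, 703 Y-assigned CpGs had at least 10 reads in KO replicate 1, and 421, 431 and 434 in WT replicates 1 and 2 and KO replicate 2. The labels give no sex of the mice.

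The same tumour had the lower X-linked level at CpG-dense DNA (21.3%). Loss of Dnmt3b as the cause of the lower X-linked level is argued against by KO replicate 2, whose X-linked level of 62.2% lay above both WT tumours. Loss of 1 X copy in part of the cells may account for it, since the X depth relative to autosomes was 0.747, below every autosome of that tumour (lowest 0.919) in every part of the X examined (0.667 to 0.808). DNA of a male animal mixed into this tumour's sample may also account for it, and of these explanations it is the one that predicts reads from Y-linked CpGs absent elsewhere. A sample in which 47.8% of cells have 1 X with unmethylated dense CpGs would have the X depth seen and a level of 20.8% there, a value that assumes such a profile and excludes neither explanation. If DNA of another animal is present, every level of KO replicate 1, on autosomes too, is a mixture. Each comparison of KO with WT given here would then be affected.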

How the results depend on the processing

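The settings with flank depth, base-change positions removed, both gene ends and whole genes were chosen only after the data were seen. Against 540 called CpGs, 2 tiles and 4 gene ends, CpG calls numbered 876 at a minimum of 5 reads and 349 at 20, and gene ends 8 and 1. Tests that ignore the spread between tumours called far more: 47619 CpGs, 5771 tiles and 386 gene ends with the likelihood ratio test, and 44522, 5732 and 384 with Fisher's exact test on pooled reads. limma on M-values called 0 CpGs, 0 tiles and 0 gene ends, with 49028, 8776 and 570 at an unadjusted p under 0.05. On autosomes 836 CpGs, 61 tiles and 21 gene ends passed, and 536 of the CpGs were among the 540. With base-change positions removed 335 CpGs, 0 tiles (9462 at an unadjusted p under 0.05) and 1 gene end passed with edgeR. Differences at Secisbp2l, Gm9370 and Mrm3 were -39.1, -22.9 and -16.5 points there at p values no higher than before, so their calls ended through the adjustment, and Dip2c had too few CpGs left to be tested. With autosomes only as well 632 CpGs, 52 tiles and 7 gene ends passed. Flank depth gave 1 tile, which was not among the 2 (adjusted p 0.0708 for Dip2c and 0.0980 for Secisbp2l), and 1 gene end. With edgeR no tile passed with the CpGs of highest coverage removed (0, 9563 at an unadjusted p under 0.05) or at 200 bp (0, 9965). At least 5 CpGs gave 1 gene end, a difference of 25 points 1, both gene ends 8 and whole genes 2.

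With reads pooled, the global difference was -2.47 points, and by number of neighbouring CpGs -2.23 at 0 to 9, -2.56 at 10 to 29, -1.41 at 30 to 59 and -3.91 at 60 or more. Leaving out 1 tumour gave 0 to 2731 CpGs, 0 to 3400 tiles and 0 to 136 gene ends with edgeR. The counts of 0 came without WT replicate 1 or WT replicate 2, with 22450 and 20385 CpGs at an unadjusted p under 0.05, and the highest without KO replicate 1. The spread between tumours then came from the pair left whole, and the lone tumour was assumed to vary like that pair. Pearson's r across CpGs was 0.977 in the WT pair and 0.957 in the KO pair. Apart from fewer tumours or features tested, the cause of the changed counts was not tested. Of 75 values of the 4 called gene ends under other settings, 44 stayed past the threshold and 31 did not. Of 28 values of the called tiles 17 stayed past it. None of these turned its direction. No gene list passed with camera in any setting run. At a minimum of 5 reads, 0 CpGs were listed within 5000 bp of the position that the gene table gives Mir196b. No paired analysis was possible because the replicate numbers follow the order of deposit and the labels tie no WT tumour to a KO tumour. With 2 tumours per group no permutation p can go below 0.33.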

Other observations

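The whole-gene values, the genes named at autosomal gene ends, the count over splits, the tests on CpG-dense DNA and the count of CpGs with clean opposite strands were chosen only after the results were seen. The setting of autosomes only was fixed before. Taken over whole genes with 1000 bp on both sides, more members of the lists were measured. Whole genes too were placed by the gene table, whose build the deposited positions do not follow, and need not be the genes named. Of 24 germline genes 15 had a lower and 9 a higher mean in KO. Adjusted over the list alone 3 passed, all lower: Sycp1, which encodes a synaptonemal complex protein, at 43.6% ± 0.636 (SD, n = 2) in WT and 29.4% ± 1.59 (SD, n = 2) in KO, Dazl, which encodes a germ cell RNA-binding protein, at 81.3% ± 1.36 (SD, n = 2) and 60.8% ± 8.11 (SD, n = 2), and Tex12. Of 18 Hox genes 11 had a higher and 7 a lower mean. Adjusted over the list alone Hoxd3 passed at 67.9% ± 8.38 (SD, n = 2) in WT and 31.5% ± 7.27 (SD, n = 2) in KO, Hoxa5 at 4.85% ± 0.0375 (SD, n = 2) and 8.81% ± 0.771 (SD, n = 2), and Hoxa10 and Hoxa11 were also higher. The window of Hoxa3 contains those of Hoxa4, Hoxa5 and Hoxa6, and Hoxa10 and Hoxa11 overlap, so the 18 members are 14 separate stretches of DNA. No member of these lists was called over all genes with edgeR (smallest adjusted p 0.0752 for germline and 0.0569 for Hox genes). The camera adjusted p was 0.315 for germline and 0.237 for Hox genes, and 0.963 for both with an estimated correlation. The mean difference of the Hox genes was -0.536 points and their median 1.43.

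Whole genes and gene ends in this paragraph were placed by the gene table, whose build the deposited positions do not follow. They need not be the genes named. Adjusted over the list alone, 4 of 19 imprinted genes and 5 of 18 genes of the mTOR and AKT list passed over whole genes. Over all genes with edgeR 0 of either passed. Inpp5f was at 51.1% ± 0.364 (SD, n = 2) in WT and 39.7% ± 0.317 (SD, n = 2) in KO, and Meg3 at 9.98% ± 0.637 (SD, n = 2) and 14.9% ± 0.447 (SD, n = 2). Rptor, which encodes a subunit of mTOR complex 1, was at 56.3% ± 0.302 (SD, n = 2) and 49.1% ± 1.35 (SD, n = 2), and Akt3, which encodes a serine/threonine kinase, at 59.9% ± 2.57 (SD, n = 2) and 73.3% ± 4.99 (SD, n = 2). The imprinted genes are 16 separate stretches of DNA. Of 8 endothelial markers 2 passed over the list alone and went both ways, Tek at 58.4% ± 2.52 (SD, n = 2) in WT and 75.2% ± 3.78 (SD, n = 2) in KO and Kdr at 39.2% ± 3.91 (SD, n = 2) and 26.6% ± 3.13 (SD, n = 2). So did 2 of 49 polycomb-regulated factors (Pax7 lower, Tlx1 higher) and 2 of 26 tumour suppressor and cancer-methylated genes (Trp73 lower, Socs1 higher). No member of these was called over all genes with edgeR. On autosomes alone the gene end of C4a, which encodes a complement component, rose from 44.2% ± 2.91 (SD, n = 2) to 61.8% ± 0.921 (SD, n = 2), that of Fam43b from 29.3% ± 1.32 (SD, n = 2) to 53.8% ± 2.83 (SD, n = 2) and that of Muc20, which encodes a mucin, from 46.5% ± 1.28 (SD, n = 2) to 78.1% ± 4.85 (SD, n = 2). That of Tmem150c fell from 55.1% ± 0.321 (SD, n = 2) to 32.1% ± 0.632 (SD, n = 2). These had an adjusted p of 0.0485 in edgeR's quasi-likelihood test, and their genes were picked after their values were seen. Over all chromosomes none of these was called, at an adjusted p of 0.0677 for Muc20, Fam43b and Tmem150c and 0.0741 for C4a. With base-change positions also removed, 7 of 21 autosomal gene ends passed and none of these was among them. Fam43b kept 2 of 4 CpGs and was not tested. The differences at C4a, Muc20 and Tmem150c did not change, at an adjusted p of 0.0556.

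Many called CpGs stood alone with large differences, which a base change in the mice could produce. A base change at the CpG as the source of all calls is argued against by 99 called CpGs where both cytosines read G on the opposite strand in all 4 tumours. For the 140 called CpGs with base-change reads, other CpGs within 50 bp moved by a median of 1.23 points, as a base change at the CpG itself predicts. For the 400 without such reads the median was 5.31 points, with 66 of 339 at 20 points or more, so this explanation stays open for a part of them. Strain haplotypes that differ between the groups may account for some, since 12 of 400 (3%) lay within 100000 bp of a base change that separates the groups, 2.70 times the share of all tested CpGs (1.11%), while loss of Dnmt3b stays open too.

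The higher level at CpG-dense autosomal DNA in KO may have more than 1 source. That tables list only CpGs with a methylated read is argued against as its cause, since with unlisted CpGs counted as unmethylated the difference was 2.07 points, with 21.7% and 23.2% in KO above 20.4% and 20.3% in WT. Incomplete bisulfite conversion in KO as the whole cause is argued against by a difference of 0.147 points at 1334 non-CpG cytosines of the same DNA, which were chosen for methylated reads by their listing. Over all non-CpG cytosines listed in each tumour the level was higher in KO, 1.54% and 1.54% against 1.35% and 1.31% in WT, a difference below the 2.66 points at CpG-dense DNA, so a small part stays open. Whether loss of Dnmt3b raised it stays open, because the exact permutation p of 0.33 is the smallest that 2 against 2 tumours allow. With reads pooled the difference over all chromosomes, X included, had the opposite sign (-3.91 points), and no autosomal pooled value was computed.

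Of the 3 splits of the 4 tumours into groups of 2, 1 gave as many called CpGs as the real one, which is the real split itself. It gave 540 calls, and the highest of the others gave 0. The other splits put 1 WT and 1 KO tumour in each group. Any difference between WT and KO, whatever its cause, then counts as spread within groups and lowers the calls. The comparison therefore does not tell causes apart, and 3 splits are too few for a share under 0.05. Both groups apart by at least 25 points were seen at 322 tiles in the real split and at 15 and 30 in the others, with the same limit.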
